A study of Arabidopsis lyrata subsp. lyrata with 8 samples.

How the data were processed

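Roots and flower buds of 6-week-old, hydroponically grown A. lyrata ssp. lyrata were compared, with 4 replicates per tissue. Per the labels' protocols, seeds were stratified for 7 days, tissue of 8 to 10 plants was pooled per replicate, total RNA was taken up in Trizol and cleaned on RNeasy columns, and it was labelled with Cy3 by a low-input amplification kit. The labels name the groups and replicate numbers, from which all samples were grouped. Roots and buds of a replicate number are not said to come from the same plants.

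The scanner files held spot intensity values that were background-subtracted and spatially detrended but not normalized between arrays, per the file headers, by Agilent Feature Extraction 10.10.1.1. Each file listed 62976 features, followed by 12 to 88 leftover lines whose complete ones repeated spots already listed; these lines were left out. The raw median intensity of a spot and of its local background, and marks for spots well above background, significantly above background, outlying or saturated, were also used, per the file headers. The authors' deposited value table held log2 values. Set against the scanner values, it matched log2 signal minus the 75th percentile of the array, centred on the median of each probe over arrays, in the same direction (r at least 0.9998 on each array). Its column medians were 0.02, -0.05, 0.06 and 0.09 for root and -0.04, -0.05, -0.03 and 0.06 for flower bud. How the authors made that table is not given in the sources used here, so this reading of scale, centring and direction rests on the match alone. No test by the authors is given either.

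Outlier spots were left out, spots of a probe were averaged, log2 of the processed signal was taken, and the 75th percentile over non-control probes was subtracted from each array; 15 probes had all spots of an array marked as outliers and were dropped. A probe counted as well above background on an array where at least 0.5 of its spots were. Gene models with 2 probes (477) were represented by the probe with the higher mean; where both probes passed (403 models), their fold changes correlated across genes at r = 0.996, and in 2 models they went opposite ways by over 1 log2 each. A gene model was tested if well above background on all 4 arrays of at least 1 tissue. This left 26420 models, of which 11623 had a locus code, and 5966 were not tested. Well above background on all arrays of both tissues were 21735.

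Array pairs were compared over probes with several spots, setting the variance of their difference against that expected from the scatter of spots within an array. Flower bud arrays 1 and 2, and 3 and 4, fell below a ratio of 1 and were averaged to 1 sample each before any test between tissues. The design fixed before the data were examined had all 8 arrays as separate samples; that fit is given as an alternative. The gene lists, the tests, the thresholds, the rule for named genes and most alternatives were also chosen before the data were examined. All arrays lay on 1 slide and were read in 1 scan, so no slide or scan could be used as a block.

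Tissues were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the data.table package, version 1.17.8, with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05 and a fold of at least 2, and every adjusted p of a gene is from this fit. The fit had 4 residual and 2.44 prior degrees of freedom, a median residual SD of 0.232 and a median standard error of 0.195 (log2). Without the fold minimum 18925 genes passed. Gene lists with at least 5 measured members were tested with limma's camera (preset correlation 0.01) against all other tested genes, adjusted over lists. They were also tested with an estimated correlation and with limma's fry, which asks whether the genes of a list move one way on balance. Tests were two-sided. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

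The scripts were tested on simulated data for this comparison with 26420 genes, in which 200 changed. At a true log2 change of 1.5, 46 of 67 were recovered (68.7%), at 2, 56 of 67 (83.6%), and at 4, 65 of 66 (98.5%). Of the unchanged genes 4 were called, and 0 changed genes had the wrong sign. Camera called 10 of 10 lists of 20 genes raised by 1 log2 and 0 of 100 unchanged lists. The simulated genes varied independently of each other and few of them changed, whereas 13606 were called in the data. In the data the estimated correlation within lists was 0.023 (root patterning) to 0.75 (hypoxia). The simulation therefore does not test whether the preset correlation of 0.01 suits these lists.

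Named genes were, for each tissue, the 6 largest fold changes among called genes well above background on all 8 arrays, the 4 largest lower bounds among genes seen in 1 tissue only, and for each tested list the 2 called members with the largest fold change in each direction, with reference genes as a range. Gene models without a locus code were passed over and counted. List members that passed in no direction, LBD41, CYP86A1, ASFT, ABCG2, ABCG20, and the members of lists too small to test were named after their values were seen. Names rest on the A. thaliana code within the model name; of the RefSeq gene table for A. lyrata, 0 entries matched a model name, so lists defined by product names were not run and positions in the genome are not used here. Close copies of a gene can bind the same probe, so members of gene families such as RBCS are uncertain as single genes.

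Alternatives were quantile normalization, equal array medians, normexp background correction (offset 50) followed by the 75th percentile or quantiles, the authors' value table, no filter on dim probes, a filter on all 8 arrays, the mean of a gene's probes, a trended and robust variance, no fold minimum, limma's treat, the replicate number as a block, other detection rules, and leaving out each array. Normexp was planned on the mean signal of a spot, a column that the scanner files used here do not hold, and used the median signal. Scaling to the E1A spike-in RNAs, all 8 arrays as samples, slide column as a block, leaving out flower bud sample A or B, and camera against genes with a code were added after the data were seen. Deviations of lists within a tissue were set against 10000 random lists of the same size matched on mean expression.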

Results

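Transcript levels were measured in roots and flower buds of Arabidopsis lyrata ssp. lyrata, a perennial relative of A. thaliana. Plants were 6 weeks old and grown in hydroponic culture, and each biological replicate was, per the labels, tissue pooled from 8 to 10 plants. The 4 root and 4 flower bud replicates were each hybridised with 1 dye, Cy3, to 1 of the 8 arrays of a single custom Agilent slide that was read in 1 scan. The array carried 32863 non-control probes for 32386 gene models, of which 12409 (38.3%) had the locus code of an A. thaliana counterpart in their name, and genes are named here by that code and its A. thaliana symbol. Well above background were 73.0% to 75.2% of the spots on the root arrays and 78.9% to 80.5% on the flower bud arrays. The 75th percentile of the signal was 2541 to 4468 on root and 4803 to 5118 on flower bud arrays, and 0 spots were saturated.

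Flower bud arrays 1 and 2 differed by less than the spots of a probe differ within an array (variance ratio 0.767), and so did flower bud arrays 3 and 4 (0.919). The other pairs of arrays within a tissue had ratios of 5.55 to 22.6. Each of these pairs was therefore counted as 1 sample, called A (arrays 1 and 2) and B (arrays 3 and 4), so that 4 root samples were compared with 2 flower bud samples. Their small number limits the precision, and p-values measure the spread between these samples. The root arrays filled 1 row of the slide and the flower bud arrays the other, so slide row and tissue cannot be told apart. Across genes, Pearson's r was 0.984 to 0.996 between root arrays, 0.984 to 0.988 between arrays of samples A and B, and 0.744 to 0.756 between tissues; genes are not independent replicates.

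The comparison asked how the transcriptomes of root and flower bud differ. Regulators of floral organ identity, genes of the anther and of pollen, genes of photosynthesis and most flavonoid genes were higher in flower buds. Genes of root hairs, of nutrient uptake, and, as 1 list, of the endodermis, the Casparian strip and suberin were higher in roots. So were those of root patterning, the meristem and the root cap, of indolic glucosinolate synthesis and of cell division. These 11 lists passed limma's camera with its preset correlation and none passed with an estimated one, where the smallest adjusted p = 0.161 with an estimated correlation. Of 26420 gene models tested, 13606 (51.5%) differed by at least 2-fold at an adjusted p under 0.05, with 6412 higher in root and 7194 higher in flower bud. At least 16-fold differences were found for 1705 gene models higher in root and 2565 higher in flower bud. Flower buds held 52.9% of the calls with each array set to its 75th percentile and 72.7% with each array set to the added spike-in RNAs, a scaling that moved the median of all genes by -0.70 on the log2 scale. With medians of the arrays made equal the median gene lay at 0.26 and flower buds held 44.9% of the calls; changes below are relative to the 75th percentile, where the median gene lay at 0.0038.

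All fold changes below are root minus flower bud on the log2 scale, ± standard error, with n = 4 root and 2 flower bud samples, so that negative values are higher in flower bud. Where a gene was not well above background on any array of a tissue, its fold is a lower bound and is written "at least N-fold". That bound sets the mean of the bright tissue against the mean, per array, of the higher of the gene's own signal and the lowest signal among probes well above background. For LDOX its own root signals were the higher throughout, so the bound equals the measured fold, which is given instead. The lowest signal used for a bound is not a detection limit, since LDOX lay above it in root without being well above background. Bounds are those under the background correction of the main fit and can fail under another. With normexp the folds of CASP2 and SHOC1 were smaller than their bounds, as given below.

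Of 9 measured regulators of floral organ identity and the flower meristem, 8 were higher in flower bud and 0 in root, with a median of -8.06 (-7.74 with bounded genes at their bound; camera adjusted p = 1.10e-04, adjusted p = 0.161 with an estimated correlation). AP1 (AT1G69120), a MADS-box gene of flower meristem and sepal identity, was at least 2029-fold higher in flower bud (adjusted p = 4.60e-08). AP3 (AT3G54340), which sets petal and stamen identity, was 753-fold higher at -9.56 ± 0.17 (adjusted p = 6.61e-08). AP2, a regulator that also acts outside the flower, was measured at 0.12 ± 0.14 (adjusted p = 0.469).

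Genes of the anther, its nutritive layer the tapetum, and the pollen wall were higher in flower bud for 16 of 18 measured members, and for 17 when adjusted over the list alone. The median was -5.79 (-5.66 with bounds; camera adjusted p = 7.28e-05, adjusted p = 0.269 with an estimated correlation). GRP19 (AT5G07550), a glycine-rich protein of the pollen coat, was at least 13506-fold higher (adjusted p = 1.53e-07), and AMS (AT2G16910), a transcription factor of the tapetum, at least 1650-fold higher (adjusted p = 5.44e-07; 2688-fold without sample A and 1013-fold without sample B). SPL, needed to form sporogenous cells, was at -2.43 ± 0.95 with an adjusted p = 0.0558 over all genes and was well above background on 1 root array. NEF1 (AT5G13390), needed for the pollen exine, was the 1 member higher in root, by 2.46-fold with a standard error of 0.20 on the log2 scale (adjusted p = 0.00115), and was at 0.59 with an adjusted p = 0.191 under spike-in scaling. The anther list also differed within flower bud, where its members were higher in sample B than in sample A by a median of 1.71 on the log2 scale; the median fold change of the list was -7.28 without sample A and -4.75 without sample B.

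Late pollen and male gamete genes were higher in flower bud for 7 of 7 members, with a median of -9.33 (camera adjusted p = 1.55e-04, adjusted p = 0.161 with an estimated correlation). VGD1 (AT2G47040), a pectin methylesterase of the pollen tube, was at -14.46 ± 0.64 (adjusted p = 2.40e-06), and AGP11 (AT3G01700), an arabinogalactan protein of pollen, at -12.12 ± 0.44 (adjusted p = 9.25e-07). Both were well above background on only 1 of the 4 root arrays, so their folds rest mostly on root signals near background.

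Nuclear genes of photosynthesis were higher in flower bud for 31 of 31 gene models, from -12.48 for RBCS1B to -2.84 for PSBR (-3.48 without root replicate 4), with a median of -5.73 (camera adjusted p = 1.61e-10, adjusted p = 0.161 with an estimated correlation). RBCS1B (AT5G38430) and RBCS3B (AT5G38410), which encode the small subunit of Rubisco, were at -12.48 ± 0.80 (adjusted p = 1.42e-05) and -12.13 ± 0.64 (adjusted p = 5.36e-06). RBCS1B, at the far end of that range, was well above background on only 2 of the 4 root arrays and was at -13.11 without root replicate 4. Its fold therefore rests partly on root signals near background. RBCS3B was well above background on all 4, but its mean root level of -6.08 was close to the -6.52 of RBCS1B. Its fold therefore also rests on low root signals. Of these gene models, 28 were well above background on all 4 root arrays.

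Of the list of flavonoid genes and MYB regulators of petals, 7 flavonoid enzymes and MYB12, a flavonol regulator, were measured and no petal MYB; 7 of these 8 were higher in flower bud, with a median of -6.23 (camera adjusted p = 0.00459, adjusted p = 0.161 with an estimated correlation). CHS (AT5G13930), chalcone synthase at the entry of the pathway, was at -10.65 ± 0.93 (adjusted p = 6.77e-05; well above background on 2 root arrays; -11.32 without root replicate 3). LDOX (AT4G22880), an enzyme of anthocyanin synthesis, was 122-fold higher at -6.93 ± 0.33 (adjusted p = 3.13e-06) and was well above background on no root array. F3H (AT3G51240), flavanone 3-hydroxylase, was higher in root at 1.05 ± 0.35 (adjusted p = 0.0320), a call that rested on root replicates 3 and 4 and on both flower bud samples. Without root replicate 4 it was at 0.78, below 2-fold, and without root replicate 3, sample A or sample B its adjusted p was 0.0514, 0.0975 and 0.130; it was at 0.34 (adjusted p = 0.477) under spike-in scaling and 0.99 with normexp and the 75th percentile.

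Root hair genes were higher in root for 12 of 13 members, with a median of 5.71 (5.26 with bounds; camera adjusted p = 6.01e-06, adjusted p = 0.161 with an estimated correlation). The class III peroxidase PER7 (AT1G30870) was at least 2892-fold higher (adjusted p = 4.07e-08) and RHS18 (AT5G22410), a peroxidase of root hair cells, at least 516-fold higher (adjusted p = 6.37e-06). PRP1, a proline-rich cell wall protein, was at 1.24 ± 0.64 (adjusted p = 0.122).

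Of 12 genes of the endodermis, the Casparian strip and suberin, 7 were higher in root and 1 in flower bud, with a median of 3.15 (camera adjusted p = 0.0121, adjusted p = 0.269 with an estimated correlation). CASP2 (AT3G11550) was at least 779-fold higher in root (adjusted p = 1.98e-07) and CASP1 (AT2G36100) was at 9.52 ± 0.41 (adjusted p = 2.01e-06; 10.14 without sample A and 8.89 without sample B). Both encode membrane proteins that place the Casparian strip. With normexp background correction and the 75th percentile CASP2 and CASP1 were at 6.74 and 8.43, and with normexp and quantiles at 6.51 and 8.34. GPAT5 (AT3G11430), an acyltransferase of suberin synthesis, was higher in flower bud at -1.89 ± 0.20 (adjusted p = 1.60e-04). Other suberin genes, CYP86A1, ASFT, ABCG2 and ABCG20, were higher in root at 7.19, 5.22, 4.94 and 1.35. ABCG6, FAR4, KCS2 and FAR5, also of suberin deposition or its fatty chains, were at 0.89 ± 0.22, 0.83 ± 0.26, 0.08 ± 0.23 and -0.92 ± 0.18, under 2-fold. These calls depended on the scaling. With equal medians ABCG6 and FAR4 passed as higher in root at 1.15 (adjusted p = 0.00536) and 1.09 (adjusted p = 0.00437). Under spike-in scaling FAR5 passed as higher in flower bud at -1.63 (adjusted p = 0.00467). ABCG20 lost its call there at 0.64 (adjusted p = 0.173), which left 6 members higher in root and 2 in flower bud. With only genes well above background on all 8 arrays the list had 10 members and lost its call (adjusted p = 0.104, the highest of the settings with the preset correlation, which began at 3.23e-04).

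Nutrient uptake and loading genes were higher in root for 16 of 23 gene models and in flower bud for 0, with a median of 2.74 (camera adjusted p = 7.28e-05, adjusted p = 0.269 with an estimated correlation). The phosphate transporter gene PHT1;2 (AT5G43370) was at least 3178-fold higher (adjusted p = 4.07e-08), and WR3 (AT5G50200), a partner protein of high-affinity nitrate transporters, was at 10.45 ± 0.23 (adjusted p = 1.36e-07). The 7 gene models that passed in neither direction lay between -0.63 for a model of HMA4, which loads zinc into the xylem, and 0.96 for BOR1, a borate exporter. Under spike-in scaling 3 members of this list were higher in flower bud.

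Of 9 genes of root patterning, the meristem and the root cap, 7 were higher in root and 1 in flower bud, with a median of 2.79 (camera adjusted p = 0.00751, adjusted p = 0.161 with an estimated correlation). BRN1 (AT1G33280), a NAC factor of the root cap, was at least 157-fold higher (adjusted p = 1.02e-06), and WER (AT5G14750), a MYB factor of epidermal cell fate, at least 122-fold higher (adjusted p = 2.21e-06). LRP1 (AT5G12330), named for lateral root primordia, was higher in flower bud at -1.80 ± 0.31 (adjusted p = 0.00207) and stayed under 2-fold with normexp background correction, at -0.86 and -0.67. WOX5, of the quiescent centre, was at 0.12 ± 0.40 (adjusted p = 0.795). With only genes well above background on all 8 arrays, 6 members remained and the list lost its call (adjusted p = 0.138, the highest of those settings, which began at 6.29e-04).

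Indolic glucosinolate genes were higher in root for 5 of 5 members, with a median of 4.44 (3.84 with bounds; camera adjusted p = 0.0125, adjusted p = 0.217 with an estimated correlation). CYP79B2 (AT4G39950), which converts tryptophan to indole-3-acetaldoxime, was at 6.41 ± 0.97 (adjusted p = 0.00102; 7.21 without root replicate 4), and the regulator MYB122 (AT1G74080) was at least 12.4-fold higher (adjusted p = 3.94e-07). The median level of the list was 0.43, 0.45 and 0.67 in root replicates 1 to 3 and -1.18 in root replicate 4.

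Genes of mitosis and cytokinesis were higher in root for 10 of 10 members, from 1.42 to 2.60 with a median of 2.06 (camera adjusted p = 0.00144, adjusted p = 0.269 with an estimated correlation). CYCB1;3 (AT3G11520), a B-type cyclin, was at 2.60 ± 0.27 (adjusted p = 1.56e-04), and KN (AT1G08560), the syntaxin of the cell plate, at 2.45 ± 0.27 (adjusted p = 2.24e-04). Under spike-in scaling the list median was 1.36 and 7 members passed.

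Of 5 genes induced by low oxygen, 3 were higher in root: SUS4 (AT3G43190), a sucrose synthase, at 3.48 ± 0.22 (adjusted p = 1.23e-05; well above background on 2 flower bud arrays), PCO1 (AT5G15120), a cysteine oxidase, at 2.39 ± 0.77 (adjusted p = 0.0283), and LBD41 at 1.57 ± 0.38 (adjusted p = 0.00906). The regulator HRA1 was at 1.45 ± 0.65 (adjusted p = 0.0869) and PDC1, pyruvate decarboxylase, at 1.16 ± 1.15 (adjusted p = 0.391). The list, with a median of 1.57, did not pass (camera adjusted p = 0.105). Its median level was 1.71, 1.21 and 1.73 in root replicates 1 to 3 and -1.89 in root replicate 4; without root replicate 4 the list passed (adjusted p = 0.00919), as it did under spike-in scaling (adjusted p = 0.0446; up to 0.155 in the other settings with the preset correlation). PCO1 was at 3.03 without root replicate 4 and lost its call without root replicate 1, 2 or 3 (adjusted p = 0.0613, 0.0625 and 0.0633), without sample A or B (0.117 and 0.0896) and under spike-in scaling (0.0724).

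Of 7 meiosis genes, 2 were higher in root and 1 in flower bud, with 5 and 1 under quantile normalization and 1 and 2 under spike-in scaling. SWI1 (AT5G51330), a protein of meiotic chromosome structure, was at 1.97 ± 0.36 (adjusted p = 0.00239), and MSH4 (AT4G17380), a crossover protein, at 1.02 ± 0.26 (adjusted p = 0.0105), while SHOC1 (AT5G52290), also of crossover formation, was at least 9.56-fold higher in flower bud (adjusted p = 9.54e-06). MSH5, SPO11-2, SDS and MND1 were at 0.86 ± 0.18, 0.60 ± 0.27, 0.38 ± 0.23 and -0.74 ± 0.17 and did not pass. The list did not pass (camera adjusted p = 0.586), and its median (0.60) and mean (0.10) were above 0 while the rotation test fry put it below 0 (direction down). The median was 1.34 under quantile normalization and turned to -0.11 under spike-in scaling. MSH4 fell below 2-fold without root replicate 1 (0.95) or 4 (0.91), and without sample B (0.94, adjusted p = 0.0660). It was at 0.32 (adjusted p = 0.567) under spike-in scaling, 0.94 with normexp and the 75th percentile and 0.99 in the authors' value table. SHOC1 was at -0.87 and -0.91 with normexp background correction, under 2-fold, so its bound did not hold there.

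The 6 gene models of common reference genes ranged from 0.02 to 1.37, and 2 of them passed: EF1A_A4 (AT5G60390), a translation elongation factor, at 1.37 ± 0.21 (adjusted p = 0.00113) and GAPC1 (AT3G04120), a glycolytic enzyme, at 1.18 ± 0.13 (adjusted p = 2.26e-04). TIP41L, the 2 models of UBQ10 and SAND were at 0.88 ± 0.11, 0.48 ± 0.21, 0.44 ± 0.23 and 0.02 ± 0.13. As a list they did not pass (camera adjusted p = 0.0886). Under spike-in scaling no member passed by limma, EF1A_A4 and GAPC1 were at 0.66 and 0.48, and both UBQ10 models and SAND turned to -0.23, -0.27 and -0.68; under quantile normalization EF1A_A4 and GAPC1 were at 0.97 and 0.84, and with normexp and quantiles at 0.90 and 0.85. With equal medians the differences grew: EF1A_A4 and GAPC1 were at 1.62 and 1.44, TIP41L passed as well at 1.14 (adjusted p = 2.10e-04), and the UBQ10 models were at 0.74 (adjusted p = 0.0314) and 0.69 (adjusted p = 0.0482), under 2-fold.

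For every list but that of the anther, the counts were the same when adjusted over the list alone. Of 17 lists written 14 had at least 5 measured members, and camera with its preset correlation called 11 of them, 6 higher in root and 5 in flower bud. With an estimated correlation camera called 0 lists, with 3 at an unadjusted p under 0.05, while fry, which does not compare a list with other genes, called 13. The other 3 lists were too small to test. In the thalianol list, triterpenes of the root, THAA2 (AT5G47950) was at least 1503-fold higher in root and THAD (AT5G47990) was at 10.71 ± 0.38 (adjusted p = 9.07e-07). In the aliphatic glucosinolate list CYP83A1 (AT4G13770) was at 6.87 ± 0.79 (adjusted p = 2.60e-04), and at 8.40 without sample A and 5.34 without sample B. Of 8 gene models of seed storage on the array 1 was tested, the oleosin OLEO2 (AT5G40420), at least 6.49-fold higher in flower bud.

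**Figure D1:**
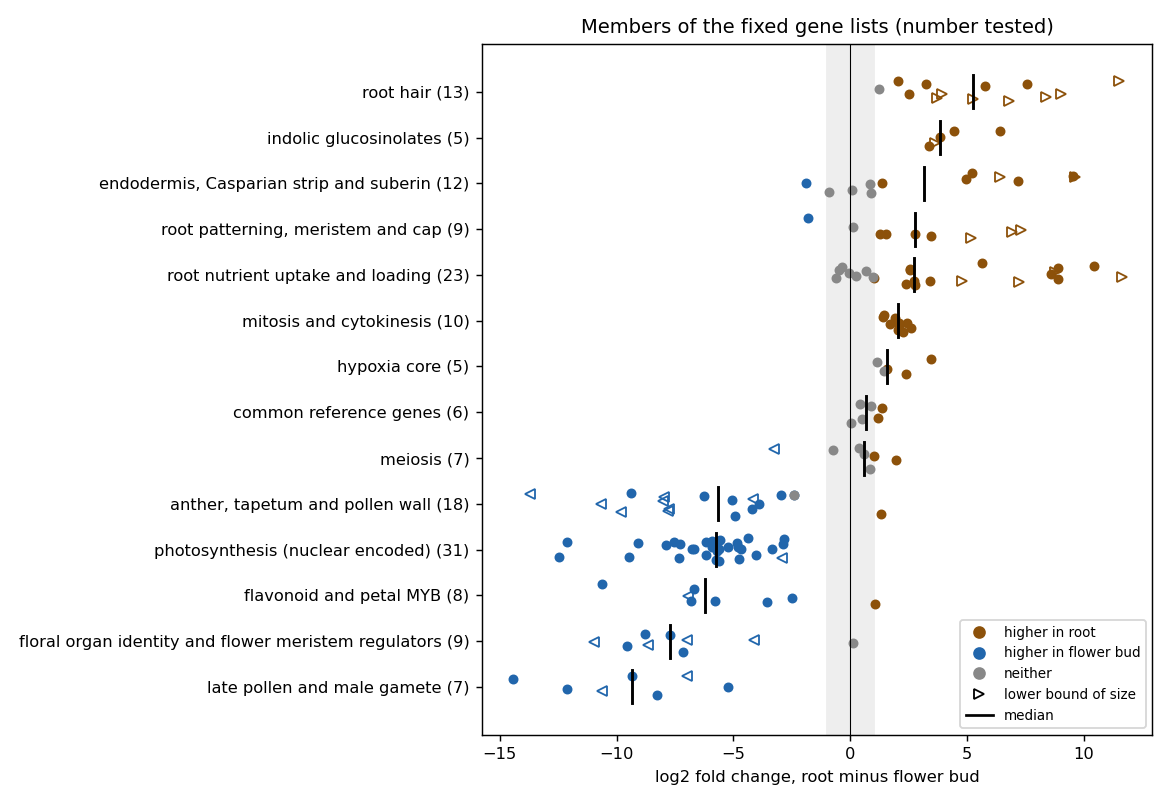
Log2 fold change, root minus flower bud, of each measured member of the 14 tested gene lists (points; open triangles are lower bounds of size; black bars are medians with bounded genes at their bound; grey band, under 2-fold). All 31 photosynthesis models lie to the left of 0, and the 10 mitosis genes to the right, as they do under each scaling tried.

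Among gene models with a locus code and well above background on all 8 arrays, which leaves out RBCS1B, VGD1 and AGP11, the largest differences higher in root were in the peroxidase gene AT3G03670 at 12.13 ± 0.18 (adjusted p = 4.54e-08), AT4G25790 at 11.41 ± 0.18, AT4G39675 at 11.37 ± 0.51, the peroxidase gene AT5G17820 at 11.34 ± 0.15, AT5G38940 at 11.32 ± 0.23 and AT5G57625 at 11.19 ± 0.37. Without sample A and without sample B, AT4G39675 was at 12.33 and 10.41, and AT5G57625 at 10.50 and 11.89. Under the same limit, those higher in flower bud were in RBCS3B, AT2G41905 at -11.80 ± 0.15, the cystatin gene AT2G31980 at -11.59 ± 0.27, AT3G28750 at -10.74 ± 0.40, AT5G50830 at -10.37 ± 0.26 and AT1G03050 at -10.17 ± 0.16. To reach these, 4 gene models without a locus code were passed over for root and 5 for flower bud. In the tissue where they were lower, the named genes had mean levels of -7.19 (AT4G25790) to -5.37 (AT3G28750). CASP1, also well above background on all 8 arrays, had a mean of -6.06 in flower bud. It went from 9.52 to 8.43 with normexp and the 75th percentile, so folds at such levels can depend on the background correction.

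Seen in root only, that is well above background on all 4 root arrays and on no flower bud array, were 814 gene models, and 2040 were seen in flower bud only. The marks were set on each array before scaling and root arrays had the lower signal, so the counts of the tissues are not directly comparable. With the laxer mark of the scanner software, significantly above background, these counts were 326 and 1063, and with well above background on at least 3 arrays of 1 tissue and at most 1 of the other they were 1201 and 2800. The largest bounds in root were at least 8641-fold for the beta-glucosidase gene AT1G66280, 7403-fold for the AT-hook gene AT3G04570, 7354-fold for the acyltransferase gene AT2G25150 and 6921-fold for AT2G33790, the arabinogalactan protein gene AGP30. In flower bud they were at least 31015-fold and 14325-fold for 2 gene models with the code of the pollen polygalacturonase AT3G07850, 16779-fold for AT3G13400 of a multicopper oxidase family, and 13506-fold for GRP19. To reach these, 8 gene models without a locus code were passed over for root and 4 for flower bud.

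**Figure D2:**
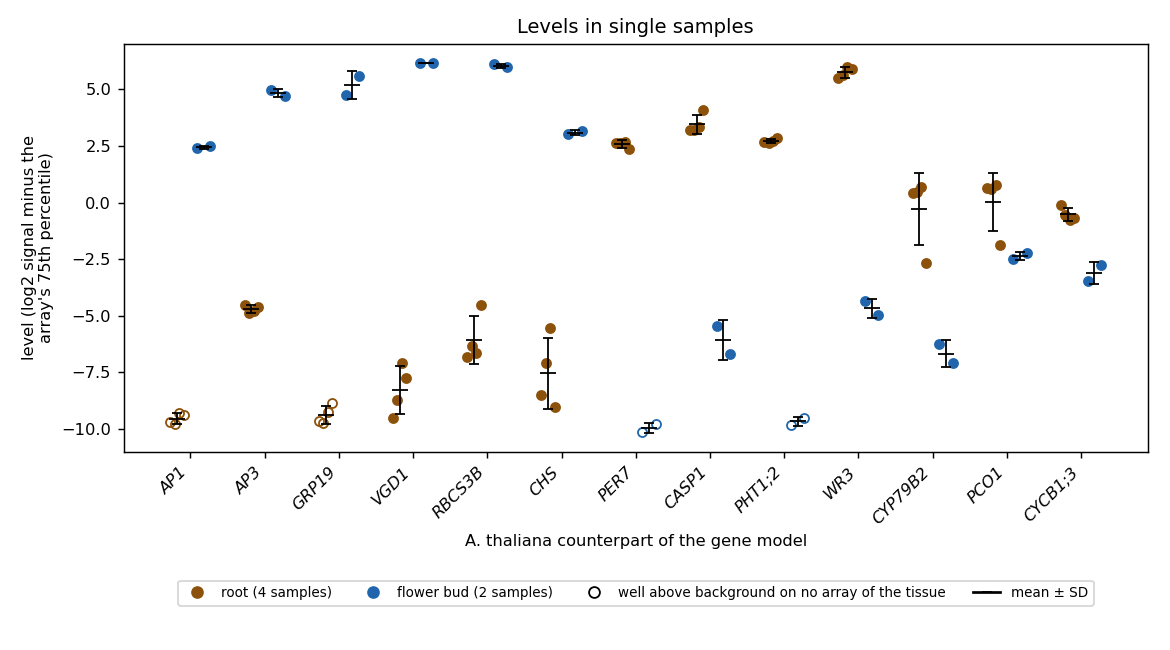
Level of 13 named genes in each of the 4 root and 2 flower bud samples (log2 signal minus the array's 75th percentile; points are samples, bars are mean ± SD; open points mark a tissue where the gene was well above background on no array). The root points of PCO1 and CYP79B2 include root replicate 4 at -1.89 and -2.66, below the other root replicates.

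**Figure D3:**
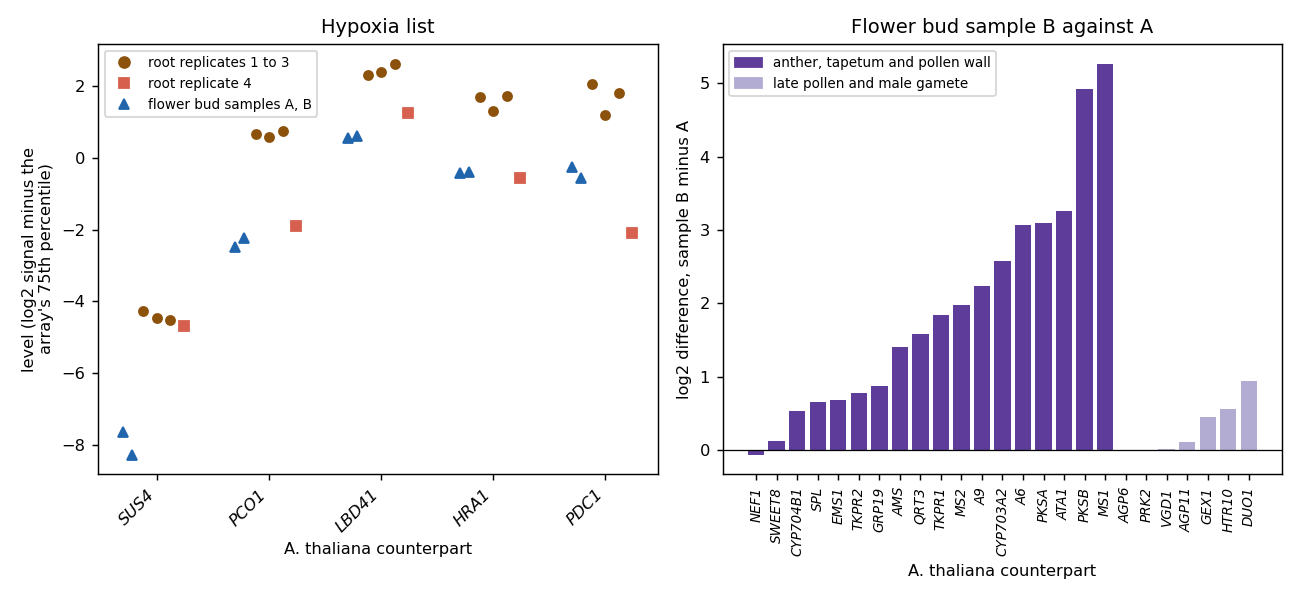
Left, level of the 5 low-oxygen genes in root replicates 1 to 3, root replicate 4 and the flower bud samples (log2 signal minus the array's 75th percentile). Right, log2 difference of flower bud sample B minus A for 18 anther and 7 late pollen genes (bars), where 17 anther genes lie above 0.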

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

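All tests of explanations for the hypoxia list reported in this part were chosen only after the result was seen.

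In root replicate 4 the 5 low-oxygen genes had a median level of -1.89, against 1.21 to 1.73 in the other root replicates, and the 5 indolic glucosinolate genes one of -1.18 against 0.43 to 0.67. A shift shared by genes of like expression was argued against, since the hypoxia list's deviation of -2.15 lay at percentile 0 of 10000 random lists of like expression. The scaling already removes a uniform shift and the list was flagged for deviating, so other effects of labelling or signal stay open. Among root arrays root replicate 4 had the lowest 75th percentile (2541) and share of spots well above background (73.0%). It also had the highest spike-in level against the 75th percentile (0.63). These measures moved in order from root replicate 1 to 4, with 75th percentiles of 4468, 3612, 2960 and 2541. The root replicates lay in slide columns 1 to 4 in that order, so root replicate 4 cannot be told apart from its place on the slide. Flower bud RNA mixed into the sample was argued against as well: the late pollen list in root replicate 4 lay at a median of -9.09 on the log2 scale relative to its flower bud level. RNA of lower quality stays open as a candidate explanation because other lists also lay outside the random lists in root replicate 4, indolic glucosinolates by -1.64, photosynthesis by -0.36 (percentile 0.02) and nutrient uptake by 0.38 (percentile 99.94), and no quality value of the RNA was used here. No biological explanation was tested, because the labels give the root replicates no different treatment.

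A root sample was taken as far from the other 3 when its gap to the nearest one made up most of the whole range, by Dixon's 95% value for 4 samples. Of 70 genes, lists and array measures tested in this way 12 passed. Chance passes about 1 in 20 for a single item, but the items share values and are not independent: the hypoxia list median in root replicate 4 is the PCO1 value, and the indolic list medians of the other root replicates span the same range as CYP79B2, a member of that list. Levels are log2 signals minus the 75th percentile of the array.

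PCO1 was at -1.89 in root replicate 4 and 0.58 to 0.77 in the others, and CYP79B2 at -2.66 against 0.43 to 0.67. AT3G28750 was at -6.34 in root replicate 4 against -5.13 to -4.90. AT2G25150 was at 3.59 there against 4.02 to 4.09, and PER7 at 2.35 against 2.65 to 2.70. Root replicate 4 was higher than the others for CASP1 (4.08 against 3.20 to 3.33), F3H (-1.10 against -2.29 to -2.11) and AGP11 (-6.35 against -7.85 to -7.70). KN was at 0.0538 in root replicate 1 against -0.46 to -0.38 in the others. AT3G13400, not well above background in root, was at -8.89 in root replicate 3 against -8.40 to -8.35.

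Among 25 control probes of the ERCC and ETG kinds, which the comparison of tissues did not use, ETG10_236652 alone had every spot well above background on all 8 arrays, with a mean level of -4.27 in root and -5.56 in flower bud. Of 308 negative control spots per array at most 5.84% were well above background.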

How the results depend on the processing

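Scaling to spike-ins, all 8 arrays as samples, the slide column block, leaving out sample A or B, and the narrower camera background were chosen after seeing the data. The number of differing genes was 13606 and ranged from 9329 (genes well above background on all 8 arrays) to 18925 (no fold minimum). In no setting was a call that was tested there reversed. That says little, since a reversal needed a gene to pass in both directions on the same data. No scaling moved the median gene further from 0 than to -0.70, under spike-in scaling. It was 13641 with quantiles, 14143 with equal medians, 11632 and 11598 with normexp, 13584 with the authors' table and 9972 with treat. Spike-in scaling gave 3964 genes higher in root and 10540 in flower bud; the spike-ins lay at a mean of 0.12 (-0.45 to 0.63) against the 75th percentile in root and -0.59 (-0.61 to -0.55) in flower bud, and which scaling is right was not tested. The filter on all 8 arrays gave 4269 genes higher in flower bud and 5 called lists, by its construction: late pollen, root hair, indolic, flavonoid and hypoxia lists then had under 5 members. The other called lists were called in every setting with the preset correlation but for the endodermis and root patterning lists under that filter; an estimated correlation left 0. Significance above background as the detection rule gave 326 genes in root only and 1063 in flower bud only, at least 3 arrays against at most 1 gave 1201 and 2800, and the rule used, asked of every probe of a gene, gave 812 and 2036. Leaving out 1 array gave 13408 to 13852 differing genes, 6334 to 6555 higher in root, 7074 to 7315 higher in flower bud, 11 to 12 lists (12 without root replicate 4), 821 to 895 genes in root only and 2051 to 2284 in flower bud only. Without sample A 13306 genes differed and without sample B 13555; the lone flower bud sample is then assumed to vary like root. For the 51 gene models named by the rule set beforehand, 1119 of 1148 values over 23 alternatives kept direction and call and 0 reversed. The other 29 lost the call, in EF1A_A4, GAPC1, F3H, MSH4, SHOC1, LRP1, NEF1 and PCO1. The rule picked called models with the largest folds or bounds in these same data, so most could hardly lose their call. Leaving out 1 flower bud array also leaves both flower bud samples in the fit. No pairing of the tissues by replicate number was seen: deviations of same-numbered arrays correlated at -0.0617, 0.0403, -0.00935 and -0.0195, and only replicate 2 matched its own number best. The replicate block gave 13765 genes against 13769 without it on 8 arrays. Flower bud arrays 1 and 2, and 3 and 4, differed by less than the scatter of spots. Separate pairings for each number could therefore hardly have shown, and whether the numbers pair the tissues stays open. The slide as a block was not run, since there was 1 slide. Signal over background limits 814 and 2040 genes to a lower bound of fold, under the background correction of the main fit.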

Other observations

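The tests on the pairs of flower bud arrays, on photosynthesis genes in root and on the percentile of the anther list were chosen only after the result was seen; so was leaving the anther list out of the test on genes higher in sample B, while that test itself and the one on gene models without a code were set before.

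Gene models with the code of a gene of the plastid genome were higher in flower bud for 33 of 37 tested, with a median of -2.10 and a range of -4.26 to -0.17; 32 to 35 passed under the other scalings and none passed as higher in root. Of 5 with a mitochondrial code 1 was higher in root and 4 passed in neither direction, and under spike-in scaling none passed.

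Flower bud samples A and B differed by at least 4-fold in many gene models, 206 higher in B and 100 in A. Genes of the tapetum and the pollen wall were among them: MS1 was higher in B by 5.27 on the log2 scale, PKSB by 4.92, ATA1 by 3.26, PKSA by 3.10 and A6 by 3.07, as described from 2 samples with no test. Late pollen genes differed by a median of 0.11 and the 10 mitosis genes were higher in B, by a median of 0.65. CYP83A1 of aliphatic glucosinolate synthesis differed by -3.05.

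The 4 flower bud arrays fell into pairs, with variance ratios of 0.767 and 0.919 against the scatter of spots. Position on the slide was looked at in root, since 1 pair lay in odd and the other in even columns. Root arrays of the odd and of the even columns deviated from the root mean with correlations of -0.213 and -0.591, the higher given first. Deviations of 4 arrays from their own mean sum to 0, so they lean to negative correlations without any effect of position. The values argue only against an effect as strong as the flower bud pattern, which would make them positive, and a weaker one stays open. Whether 1 RNA preparation was hybridised on 2 arrays stays open: the pairs were picked by a ratio of at most 1, so that the larger one was 0.919, against 5.55 or more for all other pairs within a tissue, restates the pattern and decides nothing. No biological explanation was tested, because the labels give the flower bud replicates no different condition.

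Photosynthesis genes gave signal on root arrays. Green tissue with the flower bud's own profile would, as the only source, bring all of these transcripts at 1 fraction of their flower bud level. Over 28 genes well above background on all root arrays the highest fraction was 626-fold the lowest, which argues against that narrow case. Green tissue of another profile, alone or on top of expression in root, stays open, since no leaf or other shoot tissue was measured. PSBR, at -3.48 on the log2 scale without root replicate 4 against -2.84 with it, stood at 14.0% and LHCB4.1 at 13.5% of the flower bud level, and RBCS3B at 0.0223%. A low expression of some of these genes in root itself, as a difference of tissue, stays open as untested.

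One hypothesis was that samples A and B may differ in anther stage. The median difference of the anther list, B minus A, was 1.71, at percentile 100 of 10000 random lists of like expression, with 17 of 18 members higher in B and 11 of them by at least 2-fold. This restates the difference that prompted the hypothesis and decides nothing about it. The anther list was not alone: mitosis (0.65, percentile 99.99), endodermis (0.26, percentile 99.93) and nutrient uptake (-0.15, percentile 0.30) also lay outside the central 95% of random lists, by smaller amounts. A second prediction was that genes higher in B are those of a tissue that root lacks. Of 148 gene models at least 4-fold higher in B and well above background on all flower bud arrays, 55 (37.2%) were not well above background on any root array, against 1985 of 24783 others (8.01%; odds ratio 6.79, 95% interval 4.76 to 9.61; two-sided Fisher's exact test across genes, p = 7.22e-23, genes not being independent samples). Of 65 at least 4-fold lower in B, 10 (15.4%) were so. Without the members of the anther list the counts were 50 of 141 against 1982 of 24772 (odds ratio 6.32, 95% interval 4.37 to 9.05). This compares 1 sample with 1 sample over genes and names no stage, so the hypothesis stays open. The genes were also not matched on expression level. Dim genes may both differ more between 2 samples and be marked less often on root arrays, so an odds ratio above 1 can arise without a tissue effect. The share among genes lower in B (15.4%) also lay above 8.01%.

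Of the tested gene models, 39 were at least 32-fold apart between the flower bud samples, 25 higher in B and 14 in A, and 0 of these were as far apart among the root samples. The root samples had 32 such gene models of their own, with 0 to 24 for a pair of root samples. AT2G39310 was at -10.01 in A and 0.10 in B with a root mean of -0.27, and AT3G45690 at -1.32 in A and -9.73 in B with a root mean of -0.78; both were chosen after their values were seen. AT2G39310 was not well above background on any array of A, nor AT3G45690 on any of B, so the size of each gap depends on values at background.

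A further hypothesis was that gene models without an A. thaliana code are more often restricted to flower buds. Without a code 1425 were seen in flower bud only and 550 in root only, and with a code 615 and 264, an odds ratio of 1.11 (95% interval 0.930 to 1.33; two-sided Fisher's exact test across gene models, p = 0.243), so the prediction was not met. It was 0.883 among the brighter and 1.26 among the dimmer of these models. Seen in 1 tissue only were 9.89% of the models without a code and 7.08% of those with one, a difference that was not tested.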
